A study of Rattus norvegicus with 7 samples.

How the data were processed

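The series holds 7 rat samples. CUT&RUN in the S16 Schwann cell line was done for NR2F2, YY1, RXRG and TEAD1, ChIP-seq in S16 for H3K27ac, and ChIP-seq in sciatic nerve at postnatal day 15 for SREBP1 with its input. There was 1 library per target, so that no replicate error could be computed. The 6 peak lists were analysed. No list for the input was analysed here, nor were sites of NR2F1 or SOX10, which the design text of the series mentions. The submitters' processing notes name bcl2fastq 2.20.0.422, Bowtie2, MACS2, bedtools, deepTools and build rn5, without roles, order or settings. The versions of the other tools, the thresholds of the peak calls and the use of controls are not given in the sources used here. CUT&RUN and ChIP-seq differ in fragment length and background, and peak calls depend on depth and threshold, so the number of peaks was not compared between targets as a measure of binding.

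The deposited files give positions as chromosome, start and end. The only further values are in the SREBP1 list, where the deposited score is the same in every peak and carries no ranking, and where each peak has a name ending in a number. The planned use of the highest-scoring peaks was therefore not possible, and the width of the peak took the place of the score. Coordinates are on rn5, printed counting from 1. The gene table that was at hand is of another build, so that distances to transcription start sites, gene lists near peaks and motif shares, all planned on condition of an rn5 annotation or sequence, were not run. Peaks were to be named by position in that case, the 10 highest-scoring of each list and the 10 highest-scoring NR2F2 peaks meeting the most other lists. Width replaced score in this rule, after the files were seen, and the few named are the top of those lists.

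Peaks were called shared when at least 1 bp overlapped. The share to be had by chance came from 1000 circular shifts of the second list within each chromosome, which keep the widths and spacing of peaks, with a one-sided p whose smallest value is 0.001. Stretches longer than 1 Mb without a peak in any list (14 stretches on placed chromosomes, 142 Mb in all, the longest 65.2 Mb on chromosome 4) were taken out of the axis first and were not analysed here. Intervals at 95% came from a bootstrap over blocks of 5 Mb with 1000 draws, or 300 within classes of H3K27ac peaks. Those of the differences in NR2F2 width came from 300 draws of single peaks instead. They do not allow for the clustering of peaks along the genome. Sharing of H3K27ac peaks by pairs of factors was tested by Fisher's exact test over the H3K27ac peaks, with logistic models holding the log2 width or the other factors as alternatives. The intervals of the model with all factors use standard errors clustered on those blocks. So do those of the width models fitted separately to H3K27ac peaks with and without YY1. The width model over all H3K27ac peaks does not. The models with clustered errors also hold the square of the log2 width. Widths were compared by the difference in medians with 100000 permutations. Adjacent H3K27ac peaks were stitched across gaps of up to 10 kb to describe large acetylated regions. Benjamini-Hochberg adjustment was made over the 15 pairs of lists, the 10 pairs of factors and the 5 width tests separately. Further families, outside the plan, are named where their tests are given.

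Most tests, the samples and most alternatives were fixed before the data were examined: overlap of at least 50% of the shorter peak, the midpoint rule, extension by 500 bp, independent placement of each peak, placed chromosomes only, the width model, and joining of H3K27ac peaks within 1 kb. The tests of NR2F2 width, and leaving out the widest 1% of peaks in them, used width in place of the planned score. That change was made after the files were seen. Chosen after seeing the data were the peaks wider than their list's median, shifts of 20 to 200 kb, the lower-numbered SREBP1 names, keeping the peak-free stretches, the model with all factors, and the midpoint rule for widths. The wider peaks were taken from the NR2F2, YY1, RXRG and TEAD1 lists, with H3K27ac and SREBP1 left whole. Contrasts inside and outside H3K27ac, counts of other factors at a peak and classes of H3K27ac peak width were also not in the plan. The scripts were tested on simulated data. Planted shares of 0, 2 and 30% of 41825 simulated NR2F2 peaks were recovered as 0.0754, 1.95 and 29.7%. The bootstrap interval held the true odds ratio in 94 of 100 simulated sets at a ratio of 1 and in 92 of 100 at a ratio of 4, so that it is slightly narrow. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and Matplotlib 3.10.9 were used.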

Results

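Binding sites of the orphan nuclear receptor NR2F2 were mapped in S16, a rat Schwann cell line, by CUT&RUN, in which an antibody tethers micrococcal nuclease to the protein so that it releases the bound DNA. The series also holds CUT&RUN peak lists from S16 for the zinc finger protein YY1, the retinoid X receptor RXRG and TEAD1, the DNA-binding partner of YAP and TAZ. The remaining lists come from ChIP-seq, for acetylated histone H3 lysine 27 (H3K27ac, a mark of active promoters and enhancers) in S16 and for SREBP1, a regulator of lipid synthesis genes, in sciatic nerve at postnatal day 15. The NR2F2 list held 41825 peaks, covering 15.3 Mb with a median width of 303 bp. YY1 had 38713 peaks (median 439 bp), RXRG 47951 (184 bp), TEAD1 26413 (302 bp) and SREBP1 29435, all 485 bp wide. H3K27ac had 99516 peaks, covering 92.0 Mb with a median width of 737 bp. Each target was represented by 1 library, so that the tests below describe these lists and not the spread between cultures or animals, and read depth is unknown. No control library for CUT&RUN is among the samples. Background calls in those lists could therefore not be told from binding, nor background shared by CUT&RUN libraries from shared sites.

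The first comparison asked how far NR2F2 sites in Schwann cells lie in active regulatory regions. NR2F2 peaks were concentrated in acetylated chromatin: 65.4% of them (27356 of 41825, 95% bootstrap interval 64.7 to 66.2%) shared at least 1 bp with an H3K27ac peak. Random circular shifts of the H3K27ac list gave 5.04%, a 13.0-fold difference. In the other direction, 25.5% of H3K27ac peaks (24.7 to 26.4%) held an NR2F2 peak, so that most acetylated regions of S16 lay outside the NR2F2 list. The one-sided p was 0.001, the smallest that 1000 shifts can give, also after Benjamini-Hochberg adjustment over all 15 pairs of lists. The share depended little on the definition of overlap, but the enrichment was 7.64-fold with H3K27ac peaks extended by 500 bp on each side.

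NR2F2 peaks in acetylated chromatin met other factors more often than those outside it. Inside H3K27ac peaks, 53.7% of NR2F2 peaks coincided with YY1, 45.9% with RXRG, 34.0% with TEAD1 and 17.0% with nerve SREBP1. Among the 14469 NR2F2 peaks outside H3K27ac, the shares were 5.18%, 13.7%, 5.03% and 0.809%. By share of NR2F2 peaks, RXRG was thus the most frequent partner outside acetylated chromatin, and YY1 the most frequent one inside it. Outside H3K27ac, RXRG was also the largest partner list, with 25389 peaks against 14332 for SREBP1, 6228 for TEAD1 and 5264 for YY1. Of these peaks, 8.19% of RXRG met NR2F2, against 13.7% of YY1, 12.3% of TEAD1 and 1.22% of SREBP1. These contrasts were not in the plan, and NR2F2 peaks were wider inside H3K27ac (median 348 against 249 bp). Each contrast between NR2F2 peaks inside and outside H3K27ac passed Fisher's exact test (two-sided, adjusted over 20 such tests). The odds ratios were 21.2 for YY1, 5.33 for RXRG, 9.74 for TEAD1 and 25.1 for SREBP1. Each partner list was itself enriched in H3K27ac, which tends to raise these odds ratios.

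The share of NR2F2 peaks in H3K27ac rose with the number of other factors at the site. It was 40.7% (39.8 to 41.7%) for the 19530 NR2F2 peaks with no other factor, 72.4% with 1, 93.8% with 2, 97.8% with 3 and 99.5% for the 1616 peaks with all 4. RXRG peaks followed the same course from a lower start, 21.5% with no other factor, and TEAD1 from 33.2%. YY1 peaks without another factor lay in H3K27ac in 70.8% of cases. The median width of NR2F2 peaks rose alongside, from 257 bp with no other factor to 561.5 bp with 4, and wider peaks meet every list more readily. Within the narrowest of 4 width classes of NR2F2 peaks (203 to 228 bp), a division chosen after seeing the data, the share in H3K27ac still went from 30.5% (29.3 to 31.8%) with no other factor to 64.0% with 1 and 92.6% with 2. SREBP1 peaks, all of 1 width, went from 22.9% to 98.5%. The factor lists were themselves enriched in H3K27ac (86.4% of YY1 peaks, 76.4% of TEAD1, 51.3% of SREBP1 and 47.1% of RXRG). A peak that meets them therefore tends to lie there too, which neither the width classes nor a single width removes.

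**Figure D1:**
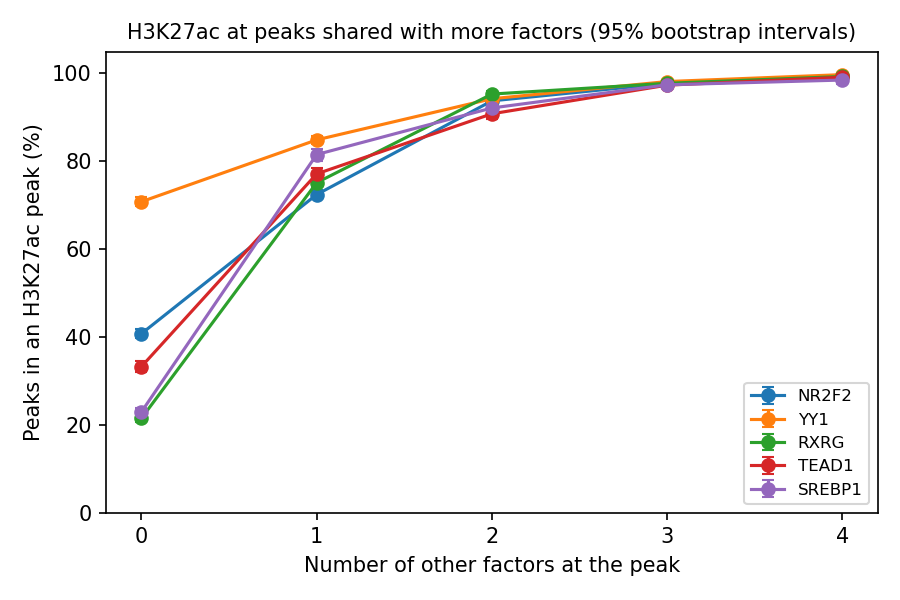
Share of each factor's peaks that lie in an H3K27ac peak (vertical axis, %) against the number of the other 4 factors at the peak (horizontal axis), 1 line per factor, with 95% bootstrap intervals. NR2F2 goes from 40.7% with no other factor to 99.5% with all 4, and YY1 starts highest, at 70.8%. The median width of NR2F2 peaks rises along the axis from 257 to 561.5 bp.

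The largest single class of NR2F2 peaks, 11574 or 27.7%, met neither H3K27ac nor any other factor, and 7956 more (19.0%) met H3K27ac alone. H3K27ac with RXRG alone accounted for 3750 peaks, against 1889 with YY1 alone and 429 with TEAD1 alone. All 5 other lists met at 1608 NR2F2 peaks (3.84%). The widest of these, which was also the widest NR2F2 peak, was at chromosome 1, 13503251 to 13506720 (3470 bp, build rn5), followed by chromosome 4, 209837473 to 209839699 (2227 bp). The peak at chromosome 14, 46855436 to 46858729 (3294 bp) met every S16 list but not SREBP1, and the widest peaks of both the YY1 and the RXRG list overlapped it, at 46855364 to 46858415 and 46856435 to 46858811. Peaks are named by position because no gene annotation of build rn5 was used here.

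The second comparison asked which of the other factors NR2F2 peaks coincide with. NR2F2 met YY1 at 36.9% of its peaks (35.7 to 38.0%), RXRG at 34.8% (34.2 to 35.5%), TEAD1 at 24.0% (23.1 to 24.9%) and nerve SREBP1 at 11.4% (10.7 to 12.1%). Against random shifts, TEAD1 was enriched 32.2-fold, RXRG 30.8-fold, YY1 28.3-fold and SREBP1 12.3-fold. All 4 pairs had a shift-based permutation p of 0.001, the smallest possible, before and after adjustment. The size of the enrichment, unlike its direction, varied with the setting: extending the second list by 500 bp gave 14.3-fold for YY1, 13.5-fold for RXRG, 15.5-fold for TEAD1 and 8.26-fold for SREBP1, and requiring the NR2F2 midpoint inside the second peak gave 45.3-fold for YY1, 52.5-fold for TEAD1 and 55.8-fold for RXRG, the last with a share of 25.3%. Shifts of only 20 to 200 kb keep the lists in their own neighbourhoods and were chosen after seeing the data. With them all 4 fell, to 22.4-fold for RXRG, 21.4-fold for TEAD1, 19.6-fold for YY1 and 9.56-fold for SREBP1. Among peaks wider than the median of their list, also chosen afterwards, all 4 rose. Both lists of a pair were cut there, except SREBP1, which stayed whole. RXRG reached 53.4-fold, TEAD1 42.5-fold, YY1 38.2-fold and SREBP1 14.7-fold. The order of the partners thus varied with the setting. With the lower-numbered SREBP1 peaks of each chromosome SREBP1 rose to 20.5-fold.

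**Figure D2:**
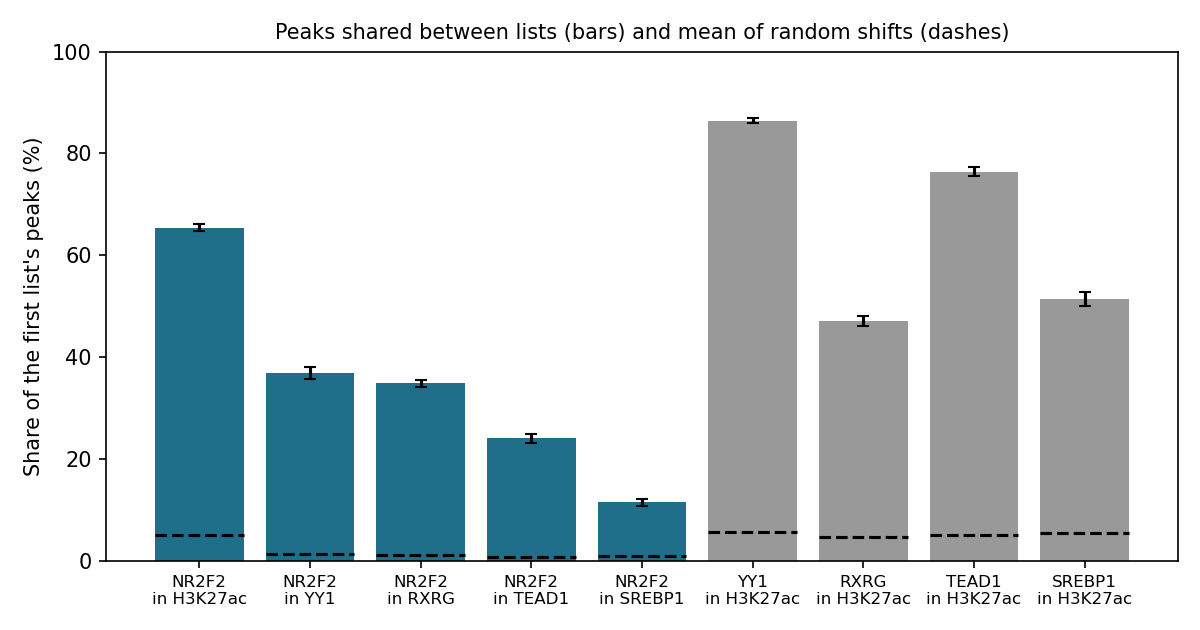
Share of the first-named list's peaks that share at least 1 bp with the second-named list (bars, %, with 95% bootstrap intervals) and the mean of 1000 random shifts (dashes), NR2F2 in blue and the other factors in grey. NR2F2 in H3K27ac stands at 65.4% against 5.04%, and YY1 in H3K27ac, the tallest bar, at 86.4%.

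NR2F2 peaks with a partner were wider. Median width was 348 bp for peaks in H3K27ac against 249 bp outside it, a difference of 99 bp (96 to 102 bp). It was 397 against 271 bp with and without YY1, 413 against 269 bp for RXRG, 427 against 281 bp for TEAD1 and 409 against 295 bp for SREBP1. Width took the place of the peak score named in the plan, since the NR2F2 list holds positions only. Each two-sided permutation p was 1e-05, the smallest that 100000 permutations can give, also adjusted over the 5 tests. A wider peak meets another list more readily by its width alone. Counting only NR2F2 peaks whose midpoint lay in the partner's peak, an alternative chosen after seeing the data, lowered the SREBP1 difference from 114 to 53 bp.

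The third comparison set the other factors against H3K27ac. YY1 was the factor most confined to acetylated chromatin, with 86.4% of its peaks (85.9 to 86.9%) in H3K27ac, followed by TEAD1 with 76.4% (75.5 to 77.3%). Nerve SREBP1 had 51.3% in the H3K27ac peaks of S16, and RXRG 47.1% (46.1 to 48.0%). Random shifts gave between 4.56% and 5.57%, and the enrichment was 15.5-fold for YY1 and for TEAD1, 10.3-fold for RXRG and 9.54-fold for SREBP1, each with a permutation p = 0.001, the smallest possible. Extension by 500 bp lowered these to 9.56, 9.52, 5.98 and 6.67-fold, and shifts of 20 to 200 kb to 8.38, 8.82, 6.80 and 5.60-fold. Of the RXRG peaks, 22993 (48.0%) met no other list, with a median width of 163 bp against 230 bp for the rest. The share that met no other list was 44.4% for SREBP1, 27.7% for NR2F2, 13.5% for TEAD1 and 7.25% for YY1.

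The largest enrichment among all 15 pairs was that of TEAD1 with YY1: 72.3% of TEAD1 peaks (71.4 to 73.2%) met a YY1 peak, 55.5-fold over random shifts. SREBP1 in nerve met YY1 in S16 at 38.6% of its peaks (37.3 to 39.9%), TEAD1 at 22.2%, NR2F2 at 16.02% and RXRG at 9.04%. These shares also depend on how much each list covers, 19.6 Mb for YY1 and 9.30 Mb for TEAD1, and over random shifts SREBP1 was enriched 26.3-fold for YY1, 26.6-fold for TEAD1, 12.3-fold for NR2F2 and 6.91-fold for RXRG.

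The fourth comparison asked which factors share the same acetylated region, taking the 99516 H3K27ac peaks as the background. Of these, 48763 (49.0%) met no factor, and such peaks raise the odds ratio of every pair. NR2F2 had its highest odds ratio with its fellow nuclear receptor RXRG, although more of its regions held YY1 (55.8%). RXRG was present in 50.7% of H3K27ac peaks with NR2F2 and in 10.1% of those without, an odds ratio of 9.14 (8.71 to 9.58), against 4.39 (4.16 to 4.62) for NR2F2 with YY1, 4.34 (4.09 to 4.57) with TEAD1 and 2.45 (2.29 to 2.60) with SREBP1. The odds ratio with RXRG was 2.08 times that with YY1 (1.94 to 2.24), and those with YY1 and TEAD1 did not differ detectably (ratio 1.01, 0.978 to 1.05). In the narrowest of 4 classes of H3K27ac peak width, RXRG (5.24, 4.69 to 5.86) was no higher than TEAD1 (5.25, 4.38 to 6.17). The RXRG odds ratio was above the YY1 one on 19 of the 20 autosomes, chromosome 10 being the exception (7.05 against 7.67). Each of the 10 pairs passed Fisher's exact test (two-sided, Benjamini-Hochberg over 10) with a p below the smallest number the software holds. The H3K27ac peaks without any factor push every pair in that direction, so that the differences between pairs say more.

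YY1 and TEAD1 formed the other close pair, with an odds ratio of 32.0 (30.4 to 33.7). TEAD1 was in 53.7% of H3K27ac peaks with YY1 and in 3.50% of those without. The odds ratio of nerve SREBP1 was also highest with YY1, at 12.7 (12.1 to 13.4), against 6.07 with TEAD1. Wide H3K27ac peaks held more of every factor, from 4.92% with YY1 in the narrowest width class to 60.0% in the widest, whereas NR2F2 went only from 15.96% to 31.4%. With the width of the H3K27ac peak in a logistic model, the odds ratio was 19.7 for YY1 and TEAD1, 8.44 for YY1 and SREBP1 and 3.46 for TEAD1 and SREBP1.

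With the other 3 factors and the width in the model, a setting chosen after seeing the data, NR2F2 with RXRG (7.27, 6.91 to 7.66), YY1 with TEAD1 (15.8, 14.9 to 16.8) and YY1 with SREBP1 (6.71, 6.31 to 7.14) remained the strongest pairs. NR2F2 stayed associated with YY1 (2.37) and TEAD1 (2.42), and weakly with SREBP1 (1.12, 1.05 to 1.19). YY1 with RXRG fell to 2.42 and TEAD1 with SREBP1 to 1.39. RXRG with TEAD1 turned from 2.95 to 0.852 (0.805 to 0.902), and RXRG with SREBP1 from 2.26 to 0.969 (0.916 to 1.02), an interval that holds 1.

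**Figure D3:**
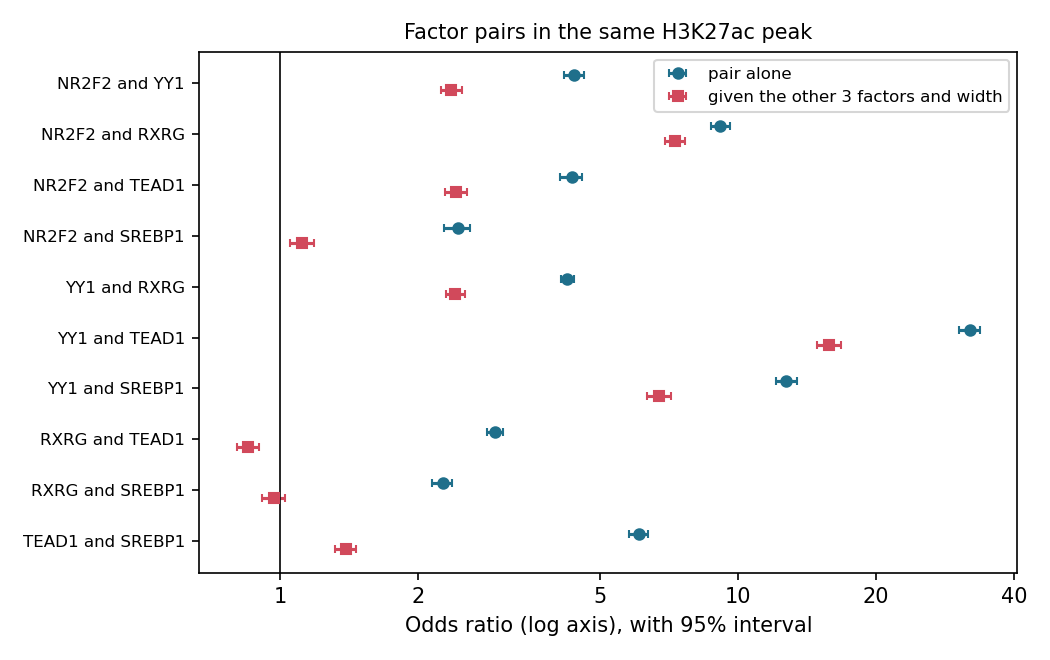
Odds ratio (horizontal log axis, with 95% intervals) for each of the 10 pairs of factors to share an H3K27ac peak, for the pair alone (circles) and given the other 3 factors and the peak's width (squares). YY1 with TEAD1 is highest, at 32.0 alone, and RXRG with TEAD1 moves from 2.95 to 0.852.

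The relation between NR2F2 and nerve SREBP1 had opposite signs in different acetylated regions. In the 30713 H3K27ac peaks with YY1, SREBP1 was present in 42.7% of those with NR2F2 and 34.3% of those without, an odds ratio of 1.43 (1.33 to 1.52). In the 68803 without YY1, SREBP1 was present in 1.58% of those with NR2F2 and 5.23% of those without, an odds ratio of 0.292 (0.251 to 0.339). RXRG with SREBP1 gave 1.17 with YY1 and 0.597 (0.527 to 0.665) without it, whereas TEAD1 with SREBP1 stayed above 1 in both, at 1.52 and 2.79. The width of the H3K27ac peak divided the pairs likewise. In the narrowest class, 231 to 367 bp, the odds ratio of NR2F2 and SREBP1 was 0.384 (0.266 to 0.505), and in the widest class it was 2.59 (2.43 to 2.78). The split by YY1 was chosen after seeing the data, and the intervals at the 5 Mb block level do not overlap.

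**Figure D4:**
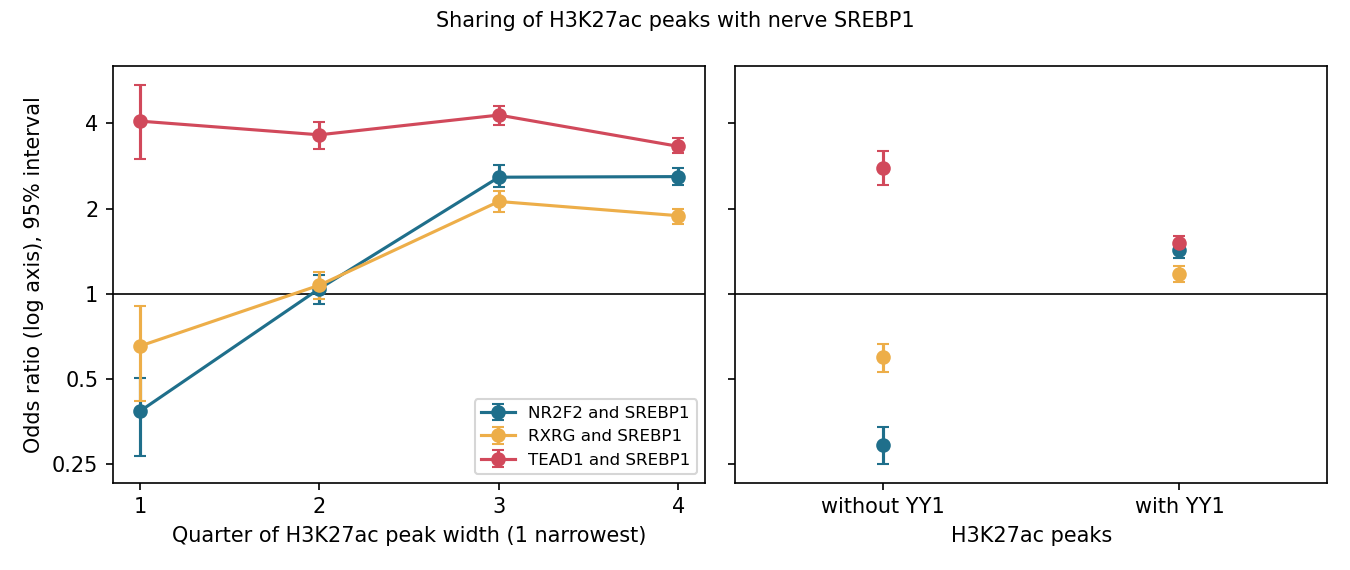
Odds ratio (vertical log axis, with 95% bootstrap intervals) for NR2F2, RXRG and TEAD1 to share an H3K27ac peak with nerve SREBP1, by class of H3K27ac peak width (left, narrowest to widest) and by the presence of YY1 (right). NR2F2 lies at 0.384 in the narrowest class and 0.292 without YY1, and above 1 in the widest class and with YY1, while TEAD1 lies above 1 throughout.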

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

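Values outside the comparisons came from the mitochondrial genome and from the names of the SREBP1 peaks, and both were looked at only after the files were seen. All 4 CUT&RUN lists held mitochondrial peaks, 13 for NR2F2, 16 for RXRG, 9 for YY1 and 9 for TEAD1. The H3K27ac list held 2 and the SREBP1 list 0.

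The number at the end of each SREBP1 peak name, used in the comparisons only for alternatives chosen after the files were seen, was related to the S16 lists. With the numbers of each chromosome divided into 4 equal ranges, 78.6% of the SREBP1 peaks in the lowest range lay in an H3K27ac peak of S16, then 47.6%, 33.7% and, in the highest range, 26.3%. The share with YY1 went from 70.4% to 12.7% and that with NR2F2 from 33.5% to 3.77%. What the number stands for is not given in the sources used here.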

How the results depend on the processing

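The 24 results were recomputed under 128 alternatives, of which 126 kept their direction and their side of the threshold. Those with the wider peaks, the short shifts, the lower-numbered SREBP1 names, the peak-free stretches kept, the other factors in the model, and the midpoint rule for widths were chosen after the data were seen. All 73 values for the 9 overlap results stayed above random placement with a permutation p = 0.001, the smallest possible, from 5.60-fold (SREBP1 in H3K27ac, shifts of 20 to 200 kb) to 55.8-fold (NR2F2 midpoints in RXRG). Short shifts gave 0.541 to 0.778 times the original enrichments, extension by 500 bp 0.440 to 0.699 times, independent placement 0.999 to 1.03 times. All 15 values for the width of NR2F2 peaks stayed positive, from 53 to 158 bp. Width took the place of score in them after the files were seen. Of the 40 values for shared H3K27ac peaks, 38 kept their side. The values that crossed 1 were RXRG with TEAD1 (0.852) and RXRG with SREBP1 (0.969), both with the other 3 factors and the width in the model. The interval of RXRG with SREBP1 (0.916 to 1.02) holds 1, so that its association was lost rather than reversed. In splits chosen after the data were seen, and not counted above, RXRG with SREBP1 gave 1.17 with YY1 and 0.597 without it, and 1.54 with NR2F2 and 1.73 without it. RXRG with TEAD1 stayed above 1 in both splits (1.14 and 1.76 with and without YY1, 2.00 and 1.17 with and without NR2F2), and the cause of its reversal in the model was not tested further. The highest-scoring peaks could not be selected, and alternatives that need gene starts, a gene annotation or sequence were not run. No paired analysis was possible because each group has 1 sample. Read depth is unknown, and its effect on the shares was not tested. In the setting with wider peaks, the NR2F2, YY1, RXRG and TEAD1 lists were each cut at their median width, while H3K27ac and SREBP1 stayed whole. The share of NR2F2 in H3K27ac was then 78.9%, with RXRG 40.8%, with SREBP1 15.7%, with YY1 34.7% and with TEAD1 21.8%. The shares with YY1 and TEAD1 were below their values in the whole lists. Those partner lists were cut too, so that this does not show that wide NR2F2 peaks met them less.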

Other observations

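The tests of explanations below, and the descriptions of placement and of chromosomes, were all chosen after the data were seen. Factors sat towards the middle of acetylated regions. In H3K27ac peaks of at least 600 bp, the central 33.3% of the peak held 53.9% of YY1 midpoints (53.3 to 54.6%), 49.7% of TEAD1, 48.5% of NR2F2, 43.5% of RXRG and 41.0% of SREBP1 midpoints. Factors in the same H3K27ac peak also met at the same place within it more often than this lean to the middle gave. The first factor's positions were exchanged between H3K27ac peaks of like width, which keeps that lean: NR2F2 met RXRG in 87.3% against 76.2%, and TEAD1 met YY1 in 96.8% against 74.5% (one-sided permutation p = 0.001, the smallest that 1000 exchanges can give, and after adjustment over 20 ordered pairs). SREBP1 with RXRG was the exception: 55.8% of SREBP1 peaks met the RXRG peak, below the 60.7% of exchanged positions, and the reverse count was 44.5% against 47.4% (both one-sided permutation p = 0.001, adjusted p = 0.01). The reverse count was not below chance when RXRG peaks were placed anywhere inside the H3K27ac peak (45.5%, one-sided permutation p = 0.053, adjusted p = 0.53). RXRG was not ahead of the other partners of NR2F2 at this level. With NR2F2 positions exchanged, observed over expected was 1.146 for RXRG, 1.148 for YY1, 1.172 for SREBP1 and 1.259 for TEAD1.

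The largest acetylated regions were comparatively poor in NR2F2 per acetylated kb, although most of them held it. H3K27ac peaks stitched across gaps of up to 10 kb formed 46130 regions, of which the top 5% by acetylated length (2306 regions) held 31.0% of that length. Per acetylated kb, NR2F2 was 0.585 times as dense there as in the other regions (0.547 to 0.628) and RXRG 0.774 times (0.732 to 0.814). The ratio was 0.961 for YY1 (0.934 to 0.990), 0.977 for SREBP1 (0.939 to 1.02) and 1.05 for TEAD1 (1.01 to 1.09). The counts include peaks in the gaps between the stitched H3K27ac peaks. Regions were ranked by the same length that divides the counts, so that a factor rising slowly with length comes out low. NR2F2 rose slowly already in single H3K27ac peaks, from 15.96% of the narrowest class to 31.4% of the widest, against 4.92% to 60.0% for YY1. The ratio may therefore not be particular to large regions. Of the top 5% of regions, 86.1% held NR2F2, against 87.8% for RXRG, 85.2% for SREBP1, 91.8% for TEAD1 and 97.6% for YY1. The region with most acetylated sequence was at chromosome 1, 105629741 to 106000992, with 71 H3K27ac, 9 NR2F2, 14 YY1, 19 RXRG, 13 TEAD1 and 10 SREBP1 peaks.

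In acetylated regions NR2F2 had a higher odds ratio with RXRG than with YY1 or TEAD1, except for TEAD1 in the narrowest regions. Weak calls in both lists would lower the odds ratio among wider peaks, with width standing in for strength, and there it was 12.6. NR2F2 with YY1 and with TEAD1 also rose there, to 5.25 and 4.63, while NR2F2 with SREBP1 was 2.41 against 2.45. Wider peaks meet other lists more readily, and strong background calls would be wide too, so that this value does not decide about poor calls. Inside H3K27ac 57.6% of RXRG peaks met NR2F2, but the widest 10% of either list there held peaks with none of the other within 500 bp: 13.6% of RXRG peaks (12.1 to 15.3%) and 13.2% of NR2F2 peaks (11.96 to 14.6%). If neither library held background calls, an RXRG signal made wholly of NR2F2 would leave strong peaks of at most 1 list outside the other. Width again stands in for strength here. Background calls particular to each library could also leave wide peaks outside the other list, so these shares do not decide the question. Whole or partial cross-reaction, a background shared by CUT&RUN libraries and joint binding, since retinoid X receptors are known partners of other nuclear receptors, stay open.

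NR2F2 and nerve SREBP1 shared fewer H3K27ac peaks without YY1 than independent placement gives. The width of the acetylated peak does not account for it, since the odds ratio without YY1 was 0.310 (0.264 to 0.363) with width in the model. RXRG with SREBP1 was likewise below 1 in the same regions (width-adjusted odds ratio 0.516, 0.452 to 0.589), but TEAD1 with SREBP1 was above it (1.95, 1.70 to 2.24), so not every S16 factor set against a list from nerve shows it. A hypothesis is that regions with YY1 may include most promoters and that NR2F2 and SREBP1 occupy different regions elsewhere, which an rn5 gene annotation would test. On chromosome X the odds ratio of NR2F2 and SREBP1 over all H3K27ac peaks was 0.412, against 1.56 to 4.50 on the 20 autosomes, and the other 3 pairs computed by chromosome were also below their autosomal range there: NR2F2 with YY1 1.35 (autosomes 3.69 to 7.67), NR2F2 with RXRG 5.90 (7.05 to 12.4) and YY1 with TEAD1 10.03 (21.9 to 43.1).

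Autosomes differed in how many S16 peaks they had for each nerve SREBP1 peak: NR2F2 from 0.804 on chromosome 17 to 2.198 on chromosome 9, and H3K27ac from 2.503 on chromosome 17 to 4.23 on chromosome 7, while chromosome X was above both ranges (2.98 and 4.28). NR2F2 and H3K27ac, each relative to a separate part of the SREBP1 list, rose and fell on the same autosomes (Spearman rho 0.872, permutation p = 1e-05, the smallest possible, adjusted p = 2.5e-05 over 10 relations; Pearson r 0.861, p = 1e-05, and 0.811 without the 2 farthest). Lists simulated to follow the SREBP1 list gave a median rho of -0.644. The SREBP1 list alone does not account for it: chromosomes 7 and 17 had 11.8 and 12.02 SREBP1 peaks per Mb but 25.2 and 9.66 NR2F2 peaks, and NR2F2 peaks per Mb rose with H3K27ac peaks per SREBP1 peak (Spearman rho 0.681, permutation p = 0.00122; Pearson r 0.804, p = 3e-05, and 0.718 without the 2 farthest). Copy number differences in the S16 line may contribute, but copy number and gene density were not measured, and regulatory differences between the line and the nerve, confounded with target and assay, stay open too.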
